A study of Mus musculus with 36 samples.

How the data were processed

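The data are RNA sequencing of dendritic cells of 2 kinds, cDC1 and cDC2, made from mouse bone marrow with FLT3 ligand and given 6 treatments, with 3 replicates in each of the 12 groups, which the series calls biological. Per the labels, RNA worth about 2000 cells went into each Smart-Seq2 reaction and libraries were made with Nextera XT and sequenced as paired ends on a NextSeq. The deposited values are expected counts per gene symbol made by the authors with RSEM on GRCm38, after demultiplexing with bcl2fastq 2.2. The RSEM version, the aligner, the annotation release and the way in which transcripts were summed to symbols are not given in the sources used here. The table holds 53299 genes and 36 sample columns, and 21% of its nonzero values are not whole numbers, so counts were rounded to whole numbers before testing. The values are not scaled to a common total, since library totals run from 3805 to 16601064.

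Groups were taken from the labels for cell type and treatment. All 36 libraries entered a single edgeR quasi-likelihood fit (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with 12 group means, TMM scaling factors and robust dispersions. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 11482 genes. The 12 treatment comparisons, the comparison of the untreated cell types and 7 interactions were tested as contrasts, 20 in all, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05 on the adjusted p. Every adjusted p of a gene in the text is from edgeR unless another tool is named. Standard errors of log2 fold changes were computed from the fold change and its F statistic, levels are CPM of TMM-scaled library totals, and their spread is the standard deviation over the libraries of a group.

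The precision of a value depends on its library. In libraries of 3805 counts, 3 counts stand for a far higher level than in the deepest library of 16601064. A fold change against a group without any count is given as a lower bound, against a floor of 3 counts per library. Where a group held 1 to 3 counts, the ratio of summed counts per scaled total is given with an exact conditional 95% interval, called the counting interval. A list median is also given with genes that had no count in 1 group set at their bound, where that changes it. Reads carry no molecular identifiers, so intervals and floors cover counting error only.

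Lists of genes for 16 pathways or processes and 9 cell types (7 genes are in more than 1 pathway list) were fixed before the data were examined, as were the comparisons, tests, alternatives and the rule for named genes. The process lists were inflammasome and pyroptosis, cytokines and chemokines, NF-kB feedback, interferon-stimulated genes, maturation and migration, MHC class I, MHC class II, cholesterol synthesis, LXR and PPAR lipid handling, NRF2 targets, integrated stress and unfolded protein response, heat shock, glycolysis and hypoxia, proliferation, lysosome and p53 targets. The marker lists were cDC1, cDC2, plasmacytoid dendritic cell, monocyte or macrophage, neutrophil or granulocyte precursor, B cell, T or NK cell, erythroid, and mast cell or basophil. A list was tested when at least 3 of its genes were. Lists were tested per comparison with camera (limma, preset correlation 0.01), which compares a list with all other genes, again with an estimated correlation, and with fry. Adjustment was over the lists of a kind within a comparison, and member counts are given over all genes tested and adjusted over the list alone.

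Genes named in the text follow the fixed rule. The first part takes called genes with a mean of at least 5 CPM in the higher group and no overlap between the 3 libraries of each group, up to 10 with the highest and 10 with the lowest log2 fold change, leaving out predicted gene models and mitochondrial genes. The second takes up to 4 members per list with the smallest adjusted p. The third is a panel: Il1b, Il6, Tnf, Il12b, Il10, Cxcl10, Ccr7, Cd40, Cd86, Nlrp3, Casp1, Gsdmd, Hmox1, Xcr1, Clec9a, Sirpa, Irf8 and Irf4. Where 10 or fewer genes were called, all are named. For interactions the first part takes 5 each way without the overlap condition, with the panel. The text names a part of these, and some genes that the rule takes are not reported here. The same rule was applied to the 23-library fit. The basophil and mast cell genes weighed in the closing section are all tested members of their list. By chance 3 libraries lie wholly above or below 3 others for 10% of genes. Positions and symbols are from GENCODE M21 on GRCm38, where 52919 of the 53299 symbols were found. Smart-Seq2 reads carry no strand, so antisense and overlapping genes cannot be told apart, and values of near-identical genes (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Olfr and Vmn1r receptors, Ccl3 and its relatives) are uncertain between copies.

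The alternatives were median-ratio (RLE) size factors in edgeR, no filter on low counts, the replicate number as a block, DESeq2 1.42.0 with its own scaling and filtering, a fit of the compared groups alone, each library left out in turn, and for the agreement between cell types a mean log2 CPM above 3. The fit without the 12 alum libraries and without replicate 6 of cDC2 with PGPC (23 libraries, 12463 genes), its median-ratio scaling, and each library left out of it, were chosen after seeing the data. The labels do not say whether the numbers pair the libraries of different treatments, and no pairing was used. No 2 libraries of a group were copies of each other. Other splits of the libraries were refitted on the compared groups alone.

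The method was tested on simulated data, made from the pooled level and fitted dispersion of each gene, with 50 genes above 5 CPM changed at each of 4 sizes. For LPS in cDC1 the fit of 36 libraries recovered 0% of genes at a log2 fold change of 1, 4% at 2, 30% at 3 and 46% at 4, and the 23-library fit 0%, 40%, 86% and 98%. For LPS with PGPC in cDC2 these were 0%, 2%, 14% and 34%, and 2%, 46%, 70% and 96%. A gene without a call can therefore have changed by several fold.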

Results

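Messenger RNA was measured in 2 kinds of conventional dendritic cell, cDC1 and cDC2, grown from mouse bone marrow with the growth factor FLT3 ligand. Each kind received 6 treatments: nothing, LPS (a bacterial cell wall product sensed by TLR4), PGPC (an oxidized phospholipid), alum (an aluminium salt used as a vaccine adjuvant), LPS with PGPC, or LPS with alum. The labels give 3 biological replicates for each of the 12 groups, so the data are 36 libraries. Replicates are numbered 1 to 3 in cDC1 and 4 to 6 in cDC2. Values after ± are standard errors for log2 fold changes and standard deviations for levels in CPM (library-scaled counts), with n = 3 libraries per group unless another number is given.

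Total counts in replicates 1, 2 and 3 of cDC1 were 2471460, 8664027 and 7450622 without treatment, 9484976, 1416289 and 2874526 with LPS, and 16601064, 2460024 and 13589259 with PGPC. They were 6121000, 8290415 and 11999793 with LPS and PGPC, 111676, 165562 and 134423 with alum, and 1856456, 3219395 and 1518413 with LPS and alum. In replicates 4, 5 and 6 of cDC2 the totals were 3351868, 3887958 and 243870 without treatment, 1892082, 1883603 and 980502 with LPS, and 2437933, 969959 and 3805 with PGPC. The remaining cDC2 totals were 8283434, 2959343 and 3982392 with LPS and PGPC, 367317, 999279 and 1074891 with alum, and 956771, 552172 and 365128 with LPS and alum.

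The 12 alum libraries stood apart from the rest. They held counts in 474 to 2627 genes, against 9760 to 15648 genes in the 23 libraries without alum other than replicate 6 of cDC2 with PGPC, which held 3805 counts in 1623 genes. Hemoglobin genes, the markers of red cell precursors, took 4.76 ± 3.42% of counts in cDC2 with alum (SD, n = 3), 3.18 ± 3.64% with LPS and alum, 2.22 ± 1.46% in cDC1 with alum and 0.211 ± 0.183% with LPS and alum. Replicate 1 of cDC1 with LPS and alum was the exception among the alum libraries, with 0 hemoglobin and 0 granulocyte counts and 1998 genes. Across the tested genes, libraries of the same alum group correlated with a Spearman rho of 0.153 to 0.645. Libraries of the same group without alum had 0.821 to 0.962, leaving out the cDC2 PGPC library of 3805 counts. TMM factors ran from 0.1395 to 5.091 with alum and from 0.4393 to 1.457 in the 23 libraries. Because 1 spread per gene is estimated over all libraries, comparisons without alum were also made with these 12 libraries and the cDC2 PGPC library of 3805 counts left out, an alternative chosen after seeing the data and called the 23-library fit here. The biological coefficient of variation was 0.833 over all 36 libraries and 0.545 in the 23-library fit.

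**Figure D1:**
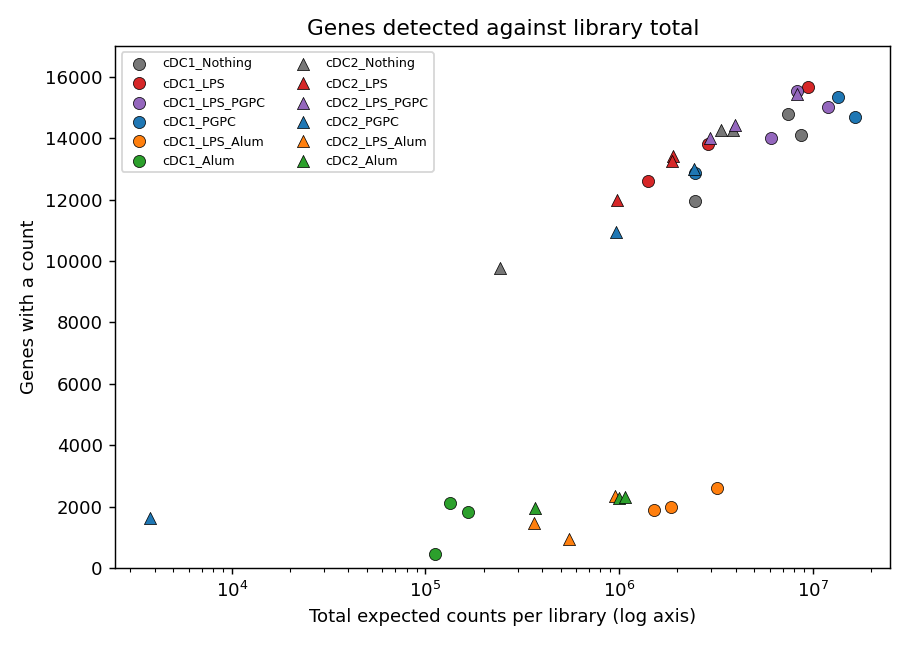
Genes with at least 1 count (y axis) against total counts (x axis, log scale), 1 point per library, coloured by treatment. The 12 alum libraries lie between 474 and 2627 genes, and 23 of the 24 others between 9760 and 15648.

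The untreated groups show which genes differ between the 2 kinds of cell as sampled in this culture. No sort or gate that would remove other cells is given in the labels. RNA of other cells therefore cannot be told apart here from marks of a kind. Genes of the plasmacytoid dendritic cell list, markers of the interferon-producing relatives of these cells, were lower in cDC2 than in cDC1: 5 of 12 (8 adjusted over the list alone) fell, among them Siglech with a log2 fold change of -6.04 ± 1.10 (0.844 ± 1.03 against 78.4 ± 61.3 CPM) and Atp1b1 with -5.00 ± 0.75, while Ly6d was at least 18.1-fold lower. The median of that list was -4.80, or -4.39 with absent genes at their bound (camera adjusted p = 1.14e-13, and adjusted p = 0.000109 with an estimated correlation). Of the cDC1 marker list 2 of 17 (5 adjusted over the list alone) fell, with a median of -2.88, or -2.29 with absent genes at their bound (camera adjusted p = 1.65e-05, and adjusted p = 0.00603 with an estimated correlation). Batf3, a transcription factor that cDC1 need, was lower in cDC2 with a log2 fold change of -5.47 ± 0.99 (adjusted p = 0.00931), and Naaa had -3.76 ± 0.70. Irf8, the other factor of cDC1 identity, had a log2 fold change of -3.47 ± 1.70 (adjusted p = 0.399), and it fell by 3.53 ± 0.47 on the log2 scale in the 23-library fit (adjusted p = 5.53e-05).

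Cd7 (log2 fold change -6.39 ± 1.11) was lower in cDC2. Higher were Dab2 (4.44 ± 0.82), Tnfrsf11a, the receptor RANK (4.73 ± 1.15), Igf2r (5.25 ± 1.09), the lipid-sensing receptor gene Pparg (4.23 ± 0.91) and the Fc receptor gene Fcgr1 (3.31 ± 0.79). Tnfrsf13c, the BAFF receptor, was 224-fold (counting interval 39.9 to 8860) higher in cDC1. Of the cDC2 marker list 0 of 13 tested members rose and 1 fell (0 and 2 adjusted over the list alone), with a median of -0.03 (camera adjusted p = 0.736). Sirpa, the standard cDC2 surface marker, reached 1.62 ± 0.47 (adjusted p = 0.0263) in the 23-library fit. Xcr1, a cDC1 surface marker, stood there at 0.365 ± 0.411 against 0.186 ± 0.202 CPM and Clec9a at -5.38 ± 1.22 (adjusted p = 0.00688). Monocyte or macrophage markers had a median of 1.46 (camera adjusted p = 0.000364, but adjusted p = 0.0984 with an estimated correlation), and 1 of 16 (1 adjusted over the list alone) rose. For B cell markers 0 of 5 tested members rose and 0 fell (0 and 2 adjusted over the list alone). Of the T or NK cell markers 0 had enough counts over all libraries to be tested.

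In all, 118 of 11482 genes differed between untreated cDC2 and cDC1 (36 higher and 82 lower in cDC2), and 1265 of 12463 in the 23-library fit (500 and 765). The share higher went from 30.5% to 69.8% under median-ratio scaling of all 36 libraries, which shifts the median of all genes by 0.537. The count fell to 42, 45 or 72 without cDC1 replicate 1, 2 or 3, and to 19, 2 or 52 without cDC2 replicate 4, 5 or 6. It was, with the 23 libraries, 666 without cDC1 replicate 2, and 702 or 537 without cDC2 replicate 4 or 5. The share of counts at the ribosomal RNA locus was 53.2 ± 16.5% in untreated cDC1 and 32.5 ± 4.45% in untreated cDC2.

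**Figure D2:**
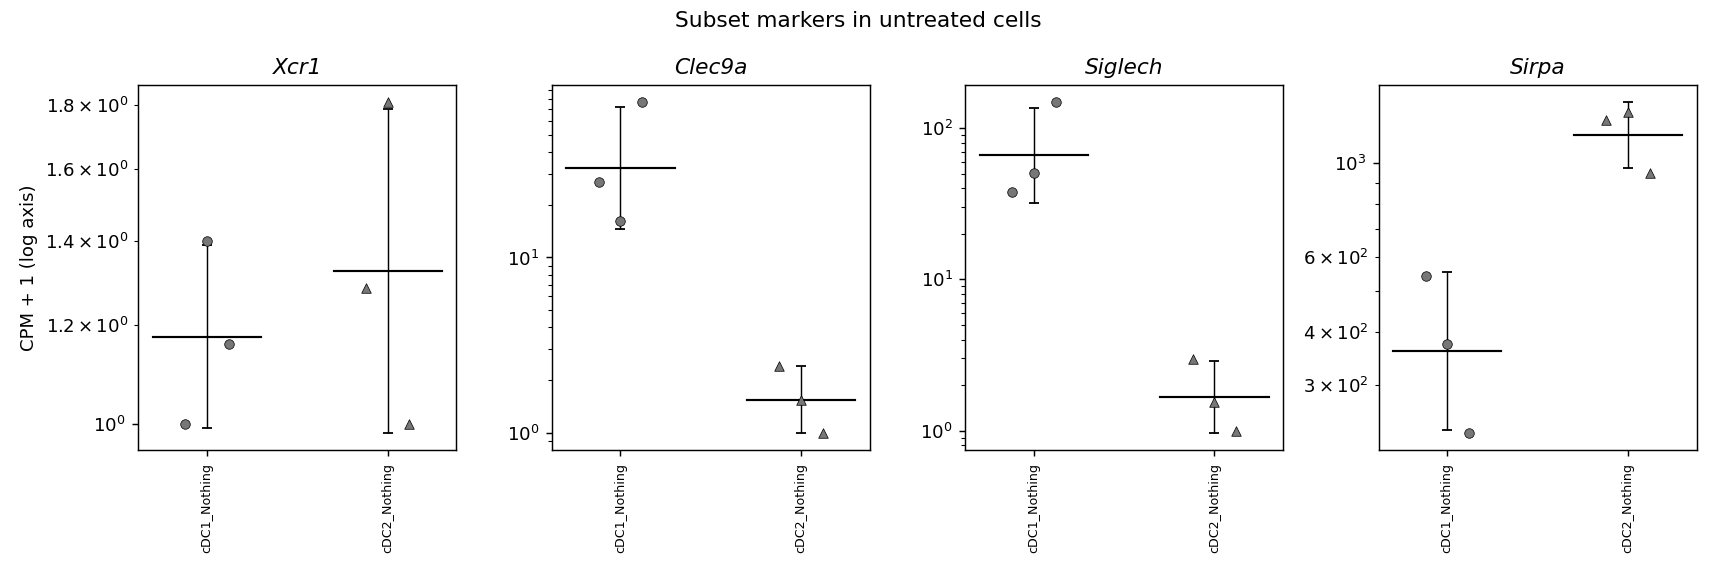
Levels of Xcr1, Clec9a, Siglech and Sirpa (CPM + 1, log axis) in untreated cDC1 and cDC2, 1 point per library, with the mean and standard deviation on the log scale. Clec9a and Siglech are lower and Sirpa higher in every cDC2 library than in every cDC1 library, and Xcr1 is near 0 in both.

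LPS alone asks how each kind of cell matures when TLR4 is engaged. In cDC1, LPS raised the transcripts of inflammatory mediators: Tnf rose by 6.16 ± 0.77 (log2, 188 ± 60.0 against 2.54 ± 1.54 CPM, adjusted p = 0.000216), Il1b by 8.88 ± 1.53 (adjusted p = 0.00154) and Ccl5 by 6.05 ± 1.22. Il12b (chromosome 11, 44400063 to 44414033 on GRCm38), the shared subunit of interleukins 12 and 23, was 464-fold (counting interval 158 to 2250) higher from 1473 counts against 3, and 281-fold without LPS replicate 1. Il6, without counts in untreated cells, was at least 68.8-fold higher. Of the cytokine and chemokine list 10 of 21 tested members rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 3.80, or 3.32 with absent genes at their bound (camera adjusted p = 1.08e-12, and adjusted p = 0.000363 with an estimated correlation). Interferon-stimulated genes moved the same way: 9 of 36 (27 adjusted over the list alone) rose, Gbp5 by 6.44 ± 1.40, Ddx58, which encodes the RNA sensor RIG-I, by 5.71 ± 1.01 and Mx2 by 4.66 ± 0.84, and the median was 4.67, or 4.48 with absent genes at their bound (camera adjusted p = 6.04e-19, and adjusted p = 0.00112 with an estimated correlation). Of the maturation list 8 of 21 (15 adjusted over the list alone) rose, including the costimulatory genes Cd86 (4.52 ± 0.70, adjusted p = 0.00105, chromosome 16, 36603869 to 36666081), Cd80 (5.22 ± 0.88) and Cd40 (6.62 ± 1.52), with a median of 3.82 (camera adjusted p = 4.98e-17, and adjusted p = 3.35e-05 with an estimated correlation). With the 23 libraries 14 of 22 cytokine and chemokine genes, 32 of 36 interferon-stimulated genes and 20 of 22 maturation genes were called higher. The lymph node homing receptor gene Ccr7 stood at 2871 ± 1730 against 57.4 ± 25.3 CPM, with 5.64 ± 1.91 (adjusted p = 0.0861) over all libraries and 5.66 ± 0.64 (adjusted p = 2.04e-06) in the 23-library fit.

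The NF-kB feedback list had 5 of 20 (11 adjusted over the list alone) members higher with LPS in cDC1, Traf1 by 6.50 ± 1.90 and Nfkbiz by 4.84 ± 1.41 (median 3.01, camera adjusted p = 2.76e-10, and adjusted p = 0.000766 with an estimated correlation). The 23-library fit called 19 of 20 higher (camera adjusted p = 1.39e-24, and adjusted p = 2.8e-05 with an estimated correlation). Inflammasome and pyroptosis genes had a median of 0.89 and 2 of 18 (4 adjusted over the list alone) rose over all libraries, the cytokines Il1a and Il1b. With the 23 libraries 6 of 18 rose, Nlrp3 among them (3.10 ± 0.58, adjusted p = 0.000481). Over all libraries Nlrp3 stood at 3.08 ± 0.97 (adjusted p = 0.0703), Casp1 at 0.88 ± 0.62 and Gsdmd at 0.55 ± 1.00 (list camera adjusted p = 0.000940, and adjusted p = 0.0347 with an estimated correlation). Marco, a scavenger receptor gene, was at least 305-fold higher, Shisa3 at least 436-fold higher, and the Notch ligand gene Dll4 was 3010-fold (counting interval 541 to 119000) higher. Cholesterol synthesis genes had a median of 1.23 (camera adjusted p = 6.81e-05, but adjusted p = 0.0526 with an estimated correlation), and 2 of 24 (4 adjusted over the list alone) rose, such as Idi1 by 3.39 ± 0.90 (10 of 24 with the 23 libraries).

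Other gene groups were lower with LPS in cDC1. For markers of other cell types, fewer such cells cannot be told apart from a response of cDC1. Of the monocyte or macrophage markers 4 of 16 (7 adjusted over the list alone) fell, such as the complement gene C1qc (-4.10 ± 0.86), C1qa (-2.98 ± 0.81) and F13a1, which was at least 23.7-fold lower. The list median was -2.48 (camera adjusted p = 0.000702, but adjusted p = 0.0919 with an estimated correlation). Plasmacytoid markers had a median of -2.05 (camera adjusted p = 0.00288, but adjusted p = 0.0919 with an estimated correlation), and 3 of 12 (4 adjusted over the list alone) fell, such as Siglech (-3.95 ± 0.91). Proliferation genes had a median of -1.08 (camera adjusted p = 0.000712, but adjusted p = 0.151 with an estimated correlation), with 3 of 26 (6 adjusted over the list alone) lower, such as Cdc20 (-3.61 ± 0.67). For the lysosome list 2 of 26 (3 adjusted over the list alone) fell, such as Atp6v0d2 (-5.58 ± 0.98; list median -0.97, camera adjusted p = 0.0121, but adjusted p = 0.236 with an estimated correlation). For LXR and PPAR lipid handling 1 of 21 (6 adjusted over the list alone) fell (median -0.95, camera adjusted p = 0.0346, but adjusted p = 0.162 with an estimated correlation). With the 23 libraries 11 of 16 macrophage, 5 of 12 plasmacytoid, 9 of 26 proliferation, 11 of 26 lysosome and 8 of 21 lipid handling genes fell (camera adjusted p = 0.00117 for lipid handling, and adjusted p = 0.0122 with an estimated correlation). Fkbp10 was at least 88.8-fold lower and the chemokine gene Cxcl14 at least 24.1-fold lower. Granulocyte precursor markers had a median of -3.52, or -3.27 with absent genes at their bound (camera adjusted p = 0.00517, but adjusted p = 0.0919 with an estimated correlation). Of the B cell markers 1 of 5 (3 adjusted over the list alone) fell (camera adjusted p = 0.109). The medians of the lipid handling, proliferation and lysosome lists turn positive when all 36 libraries are scaled by median ratios, which rest on the 12 genes counted in every library. With the 23 libraries, where 7395 genes carry that scaling, they stay negative.

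The remaining lists were not called in cDC1 with LPS over all libraries, or only weakly. MHC class I genes had a median of 0.97 with 0 called (camera adjusted p = 0.0284, but adjusted p = 0.182 with an estimated correlation) and MHC class II genes 0.70 with 1 of 12 (1 adjusted over the list alone) higher (camera adjusted p = 0.131). The 23-library fit called 6 of 16 class I genes higher (camera adjusted p = 0.00229, but adjusted p = 0.0582 with an estimated correlation). Of the class II genes it called 5 of 12 higher and 1 lower (camera adjusted p = 0.0131, but adjusted p = 0.274 with an estimated correlation). The median was -0.40 for NRF2 targets (camera adjusted p = 0.654), 0.35 for the integrated stress and unfolded protein response (adjusted p = 0.287), 0.03 for heat shock genes (adjusted p = 0.799), -0.17 for glycolysis and hypoxia (adjusted p = 0.654) and 1.00 for p53 targets (adjusted p = 0.131). Of the p53 targets 5 of 17 rose with the 23 libraries (camera adjusted p = 0.0253, but adjusted p = 0.0636 with an estimated correlation). For NRF2 targets and glycolysis the median was below 0, or above 0 under median-ratio scaling of all 36 libraries, while the test pointed upward. The cDC1 marker list had a median of -0.92 (adjusted p = 0.418, positive under that scaling) and the cDC2 marker list 0.68 (adjusted p = 0.355), which turned to -0.20 in the 23-library fit. Erythroid markers had a median of 0.00 (adjusted p = 0.710). Mast cell or basophil markers had 3.11, or 1.01 with absent genes at their bound (adjusted p = 0.0491, but adjusted p = 0.0919 with an estimated correlation).

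Over all libraries LPS changed 596 of 11482 genes in cDC1 (228 higher, 368 lower), and 2235 of 12463 in the 23-library fit (1069 higher, 1166 lower), which included all 596. The count was 231, 269 or 321 without LPS replicate 1, 2 or 3, and 348 or 349 without untreated replicate 2 or 3. Among the 23 libraries it was 1448 or 1445 without LPS replicate 1 or 2. Tnf, Il1b, Il12b, Cd86, Cd80, Gbp5, C1qc and Marco kept their calls under every setting and with each library left out. The calls of Cd40, Ccl5, Il6, Traf1, Nfkbiz, Cdc20 and Siglech were lost in at least 1 (highest adjusted p = 0.0503, 0.206, 0.0794, 0.145, 0.169, 0.0709 and 0.138). These 7 genes, by the 23-library fit, kept their calls whichever library was left out, with a highest adjusted p of 0.00559 for Siglech. The median log2 fold change of all genes shifts by 1.31 under the median-ratio scaling of all 36 libraries, and the share of called genes that are higher goes from 38.3% to 88.8%. The ribosomal RNA locus took 53.2 ± 16.5% of counts in untreated cDC1 and 21.9 ± 6.86% with LPS, without overlap between the libraries.

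**Figure D3:**
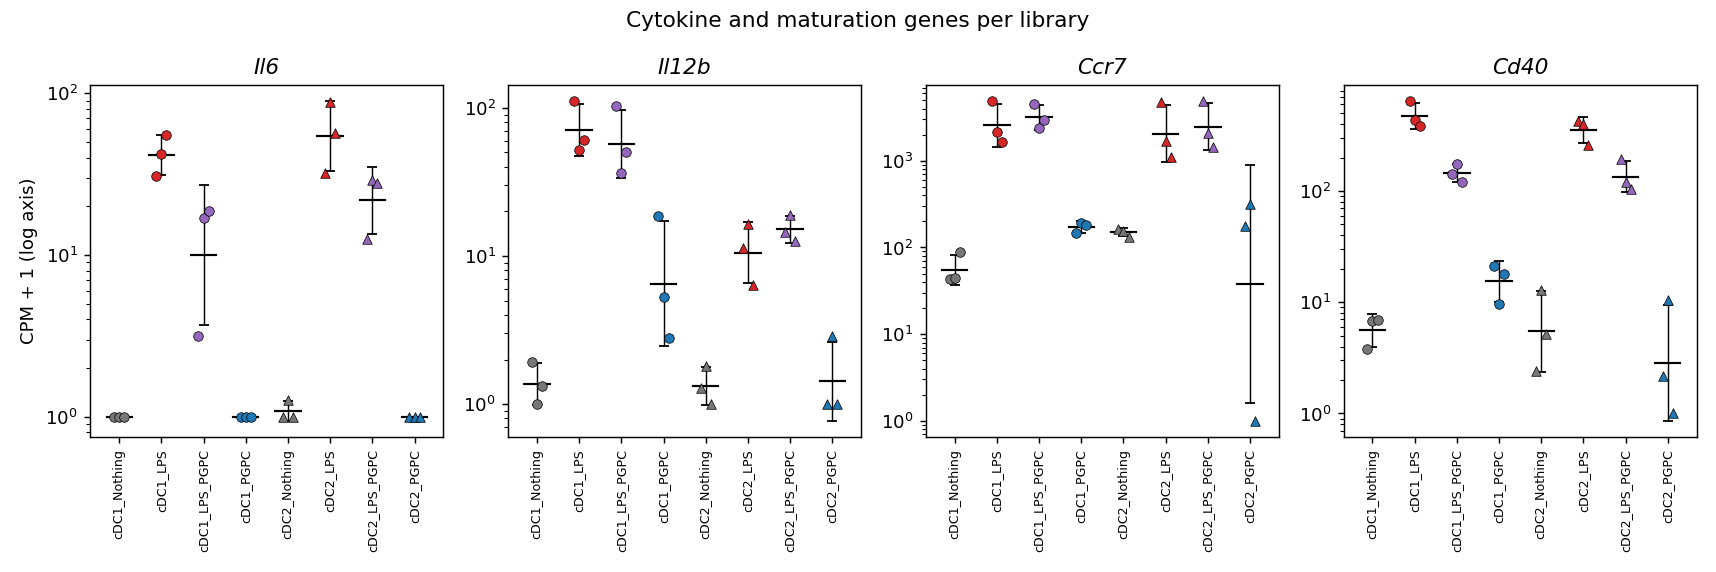
Levels of Il6, Il12b, Ccr7 and Cd40 (CPM + 1, log axis) in the 24 libraries without alum, 1 point per library, with the mean and standard deviation on the log scale. In both kinds of cell each LPS library lies above each untreated library for all 4 genes.

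In cDC2, LPS raised many of the same kinds of gene. Ccl5 rose by 7.31 ± 1.29 (adjusted p = 0.00193), Il1b by 7.07 ± 1.41 (516 ± 239 against 3.88 ± 1.46 CPM), Tnf by 3.35 ± 0.67 and Il12b by 4.25 ± 1.07, while Il1a was 680-fold (counting interval 232 to 3300) higher. Il6 went from 1 to 252 counts, 426-fold (counting interval 75.7 to 16900), without a call (adjusted p = 0.0638). Of the cytokine list 8 of 21 (18 adjusted over the list alone) rose (median 4.13, camera adjusted p = 4.73e-20, and adjusted p = 7.58e-06 with an estimated correlation). Interferon-stimulated genes had 6 of 36 (27 adjusted over the list alone) higher, Gbp3 by 5.16 ± 0.95 and Mx2 by 3.81 ± 0.75 (median 4.01, camera adjusted p = 6.17e-25, and adjusted p = 4.71e-05 with an estimated correlation). The maturation list had 5 of 21 (13 adjusted over the list alone) higher: Cd86 by 4.51 ± 0.72, Cd200 by 4.44 ± 0.69 and Cd40 by 5.87 ± 1.49 (median 3.47, camera adjusted p = 6.07e-20, and adjusted p = 7.58e-06 with an estimated correlation). Ccr7 stood at 4.07 ± 1.78 (adjusted p = 0.347), with 4.06 ± 0.59 (adjusted p = 5.97e-05) in the 23-library fit. MHC class I genes had a median of 2.45 with 0 of 16 (1 adjusted over the list alone) higher (camera adjusted p = 1.78e-06, and adjusted p = 0.00567 with an estimated correlation), and in the 23-library fit H2-K1 rose by 2.54 ± 0.38. NF-kB feedback genes had 2 of 20 (13 adjusted over the list alone) higher, Nfkbie by 2.84 ± 0.66 (median 2.97, camera adjusted p = 3.16e-13, and adjusted p = 6.33e-05 with an estimated correlation). Inflammasome genes had 2 of 18 (7 adjusted over the list alone) (median 1.04, camera adjusted p = 0.000310, and adjusted p = 0.0136 with an estimated correlation). With the 23 libraries 16 of 22 cytokine, 29 of 36 interferon-stimulated, 20 of 22 maturation, 12 of 16 MHC class I, 18 of 20 NF-kB feedback and 7 of 18 inflammasome genes were called higher. MHC class II genes had 6 of 12 higher there (camera adjusted p = 0.000117, but adjusted p = 0.104 with an estimated correlation).

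Lower with LPS in cDC2 were Pparg (-5.07 ± 1.02, adjusted p = 0.0104), the monocyte chemokine receptor gene Ccr2 (-4.10 ± 0.93) and the cell cycle phosphatase gene Cdc25b, 46.6-fold (counting interval 15.7 to 228). Proliferation genes had a median of -1.46 with 2 of 26 (3 adjusted over the list alone) lower, such as Ccna2 (-2.83 ± 0.71) (camera adjusted p = 4.9e-10, and adjusted p = 0.00567 with an estimated correlation). LXR and PPAR lipid genes had a median of -0.98 (camera adjusted p = 0.000310, and adjusted p = 0.0118 with an estimated correlation): Pparg fell, and Nr1h3, which encodes LXR alpha, rose by 3.66 ± 0.94. Lysosome genes had 1 of 26 (1 adjusted over the list alone) lower (median -0.59, camera adjusted p = 0.0112, but adjusted p = 0.296 with an estimated correlation). Cholesterol synthesis genes had a median of 0.25 while the test pointed downward (camera adjusted p = 0.802).

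LPS changed 232 genes in cDC2 (159 higher, 73 lower), and 1062 in the 23-library fit (725 higher, 337 lower), which included all 232. Without LPS replicate 4, 5 or 6 the count was 126, 120 or 139, and without untreated replicate 4, 5 or 6 it was 31, 79 or 87, while the 23-library fit gave 652 without untreated replicate 4. Cd86, Cd200 and Cdc25b kept their calls under every setting and with each library left out. The calls of Ccl5, Il1b, Tnf, Il12b, Pparg, Cd40, Ccr2 and Ccna2 were lost in at least 1 (highest adjusted p = 0.212, 0.111, 0.163, 0.288, 0.0599, 0.218, 0.106 and 0.183).

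Across the 11482 genes the log2 fold changes of LPS in cDC1 and cDC2 had a Pearson r of 0.511 and a Spearman rho of 0.48, where genes are not independent replicates. Higher in both were 79 genes, against 3.16 if the 2 sets were independent (Fisher's exact test p = 1.49e-95). Lower in both were 29 against 2.34 (Fisher's exact test p = 8.25e-25), and 1 went opposite ways. The test of the difference itself called 6 genes, all with a higher log2 change in cDC2, among them Cxcl14, Tnfrsf13c, Cst7, Enpp4 and C130026I21Rik. Cst7, which encodes cystatin F, had an interaction of 7.21 ± 1.09 (adjusted p = 0.00742). The same test called, in the 23-library fit, 166 genes (124 higher, 42 lower in cDC2), among them Tnf with a weaker rise in cDC2 (-2.94 ± 0.71, adjusted p = 0.0357, and up to 0.187 with 1 library left out) and Hmox1 with a difference of 2.56 ± 0.59 (adjusted p = 0.0263, up to 0.118). The 6 became 0 without untreated cDC2 replicate 5 and 17 without cDC1 LPS replicate 3, and it was 0 under median-ratio scaling of all 36 libraries.

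Adding PGPC to LPS asks what distinguishes cells given both, a combination used to bring dendritic cells into the hyperactive state that the series is about, from cells with LPS alone. In cDC1, 8 genes changed. Klf2, which encodes a Kruppel-like transcription factor, rose by 5.03 ± 0.91 (20.5 ± 9.73 against 0.522 ± 0.473 CPM, adjusted p = 0.0374, chromosome 8, 72319033 to 72321656), Acss2, an acetyl-CoA synthetase of the SREBP program, by 2.78 ± 0.52, and Mgst3, a glutathione transferase, by 3.29 ± 0.54. Rhoc rose by 3.61 ± 0.68, Tgfb1i1 by 4.67 ± 0.88 and 4930523C07Rik by 3.10 ± 0.53, Fhl2 was 96.0-fold (counting interval 17.0 to 3810) higher (45.4-fold without LPS and PGPC replicate 1), and Fam43a fell by 4.25 ± 0.73 on the log2 scale. By the 23-library fit 241 genes changed (173 higher, 68 lower). They included the lipid droplet gene Plin2 (2.62 ± 0.36, adjusted p = 0.000681), the lipoprotein lipase gene Lpl (3.39 ± 0.45, adjusted p = 0.000469), Pparg (3.23 ± 0.80), the cholesterol synthesis genes Fdps (1.85 ± 0.38) and Fdft1 (2.42 ± 0.62), and the MHC class I genes H2-D1 (2.18 ± 0.43) and H2-K1 (1.73 ± 0.36). The LPS-induced genes Shisa3 (-4.82 ± 0.78) and Ebi3, a subunit of interleukin 27 (-2.81 ± 0.51), were lower.

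Of the LXR and PPAR lipid handling list in cDC1 with LPS and PGPC 0 of 21 (1 adjusted over the list alone) rose, with a median of 0.86, or 0.81 with absent genes at their bound (camera adjusted p = 0.0298, but adjusted p = 0.457 with an estimated correlation). In the 23-library fit it was 3 of 21 (8 adjusted over the list alone) with a median of 0.83 (camera adjusted p = 0.000387, and adjusted p = 0.00819 with an estimated correlation). MHC class I genes had a median of 0.71 there with 2 of 16 (3 adjusted over the list alone) higher (camera adjusted p = 0.000465, but adjusted p = 0.0778 with an estimated correlation) and lysosome genes 0.64 with 3 of 26 (10 adjusted over the list alone) (camera adjusted p = 0.00230, but adjusted p = 0.267 with an estimated correlation). NF-kB feedback genes had a median of -0.66 (camera adjusted p = 0.000790, but adjusted p = 0.0992 with an estimated correlation). Proliferation genes over all libraries had a median of -0.47 (camera adjusted p = 0.00700, but adjusted p = 0.457 with an estimated correlation). The inflammatory genes Il1b (0.42 ± 1.06), Tnf (-1.40 ± 0.62), Il12b (-0.25 ± 0.74), Cd40 (-1.74 ± 1.22), Nlrp3 (-1.23 ± 0.91), Casp1 (0.58 ± 0.60) and Gsdmd (0.90 ± 1.00) were not called against LPS alone, and Il1b and Casp1 change sign under median-ratio scaling of all 36 libraries. In simulated data for this comparison the fit of 36 libraries recovered 0% of genes at a log2 fold change of 2 and 6% at 3. A missing call therefore does not show that these genes were unchanged.

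The count of 8 depended on single libraries. It was 0 without LPS replicate 1 or 2 or LPS and PGPC replicate 1 or 3. It was 4 without LPS replicate 3 and 30 without LPS and PGPC replicate 2. Under median-ratio scaling, and with the replicate number as a block, it was 0. In the 23-library fit it was 74 or 67 without LPS replicate 1 or 2, and 147 or 101 without LPS and PGPC replicate 1 or 3. Among the 23 libraries Klf2, Acss2, Mgst3, Rhoc, Tgfb1i1, Fam43a, Plin2 and Lpl kept their calls whichever library was left out (highest adjusted p = 0.0400 for Tgfb1i1). Total counts were 8804000 ± 2973000 with LPS and PGPC and 4592000 ± 4300000 with LPS.

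In cDC2 with LPS and PGPC against LPS, cholesterol synthesis genes were higher as a group: their median log2 fold change was 1.56 over 24 tested members (camera adjusted p = 2.53e-17, and adjusted p = 0.000410 with an estimated correlation), with 0 called singly over all genes and 0 adjusted over the list alone. In the 23-library fit the median was 1.55 and 2 of 24 (16 adjusted over the list alone) rose (camera adjusted p = 1.15e-21, and adjusted p = 0.000240 with an estimated correlation), Fdps by 1.95 ± 0.40 and Msmo1 by 1.99 ± 0.36. LXR and PPAR lipid handling genes had a median of 0.53 with 0 of 21 (1 adjusted over the list alone) (camera adjusted p = 0.000247, and adjusted p = 0.0199 with an estimated correlation). Plin2 rose in the 23-library fit by 2.60 ± 0.36 (adjusted p = 0.000698) and Lpl by 2.38 ± 0.43. Single genes called over all libraries were Klf2, 109-fold (counting interval 19.4 to 4300) higher from 326 counts against 1, and Cdc25b, 28.6-fold (counting interval 9.69 to 140) higher. The 23-library fit called 48 genes (35 higher, 13 lower, or 61.5% higher in place of 72.9% under median-ratio scaling), among them the glucocorticoid-induced gene Tsc22d3 (3.83 ± 0.41, adjusted p = 1.35e-05), Nrp1 (3.68 ± 0.45) and Rhob (3.44 ± 0.53). Nlrp3, the inflammasome sensor (-3.02 ± 0.55, adjusted p = 0.00689), and the NF-kB target Sod2 (-2.12 ± 0.33) were lower there.

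NF-kB feedback genes in cDC2 had a median of -0.79 with LPS and PGPC (camera adjusted p = 0.000575, but adjusted p = 0.0578 with an estimated correlation), and -0.79 with 1 of 20 (2 adjusted over the list alone) lower in the 23-library fit (camera adjusted p = 7.23e-09, and adjusted p = 0.00300 with an estimated correlation). Cytokines and chemokines had a median of -0.80 (camera adjusted p = 0.00113, but adjusted p = 0.0752 with an estimated correlation), and in the 23-library fit -0.83 (camera adjusted p = 2.01e-05, and adjusted p = 0.0416 with an estimated correlation). The integrated stress list had a median of 0.19 (camera adjusted p = 0.00970, but adjusted p = 0.205 with an estimated correlation) and p53 targets 0.21 (camera adjusted p = 0.0217, but adjusted p = 0.0578 with an estimated correlation). Monocyte or macrophage markers stood at 0.71 (camera adjusted p = 0.0365, but adjusted p = 0.486 with an estimated correlation). Both calls over all libraries were lost with any 1 of the 6 libraries left out. They were also lost under median-ratio scaling and with the replicate number as a block. The 23-library count was 88, 27 or 19 without LPS replicate 4, 5 or 6 and 26 or 19 without LPS and PGPC replicate 4 or 5. Klf2, Cdc25b, Tsc22d3, Nrp1, Plin2, Sod2 and Rhob kept their calls in each of these (highest adjusted p = 0.0466 for Klf2), and Nlrp3 and Lpl did not (0.0863 and 0.0618). Totals were 5075000 ± 2825000 with LPS and PGPC and 1585000 ± 523900 with LPS.

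**Figure D4:**
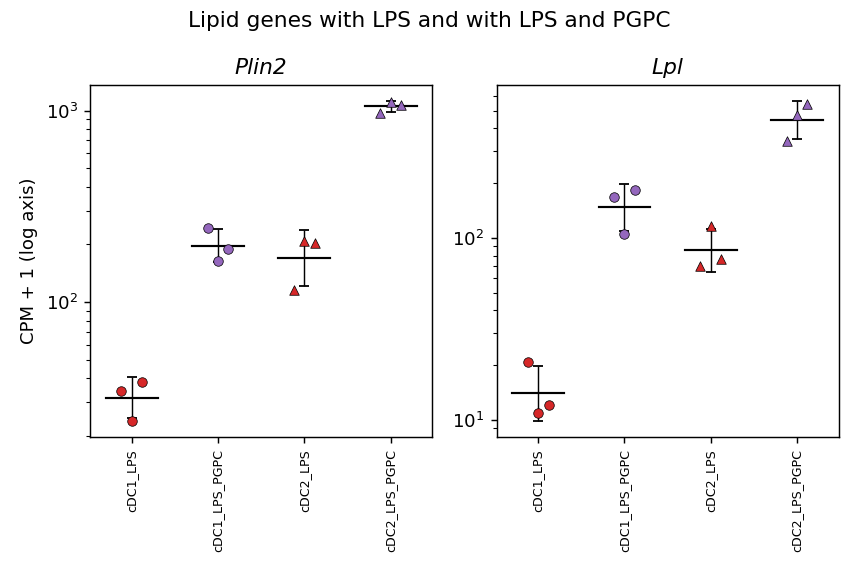
Levels of Plin2 and Lpl (CPM + 1, log axis) in the 12 libraries with LPS alone or LPS and PGPC, 1 point per library, with the mean and standard deviation on the log scale. Plin2 and Lpl are higher with LPS and PGPC than with LPS alone in both kinds of cell in the 23-library fit. Untreated levels, above those with LPS alone, are not shown.

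Across genes the change from adding PGPC to LPS had a Pearson r of 0.217 (rho 0.219) between cDC1 and cDC2. It was 0.0436 without cDC2 LPS replicate 4 and 0.33 or 0.105 without cDC2 LPS and PGPC replicate 4 or 6. Klf2 was higher in both, against 0.00122 genes for independent sets. Of the 23-library calls, 19 genes were higher in both (0.486 for independent sets, Fisher's exact p = 6.21e-27) and 4 lower in both (0.0709, p = 5.58e-07). The test of the difference between the cell kinds called 0 genes (edgeR, with 362 at an unadjusted p under 0.05; DESeq2 called 15), and 1 in the 23-library fit: Nrp1, higher with PGPC in cDC2 relative to cDC1 by 3.94 ± 0.58 (adjusted p = 0.00498).

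PGPC without LPS asks what the lipid does to resting cells. In cDC1 Il12b was 55.2-fold (counting interval 18.8 to 269) higher from 463 counts against 3 (adjusted p = 0.0388), with 425 of the 463 in PGPC replicate 1, and 10.8-fold without that library. Prss34, a protease gene of basophils and mast cells, was at least 63.4-fold higher (38.4 ± 10.3 CPM against no counts). Parp12, Hs3st3b1, Tspan9 and Flt4 had no counts with PGPC and were at least 81.9-fold lower, at least 67.0-fold lower, at least 43.9-fold lower and at least 38.0-fold lower. Of 43 genes called 5 were higher and 38 lower. The 23-library fit called 259 (72 higher, 187 lower), including all 43. It held the chemokine genes Ccl22 (3.15 ± 0.52) and Ccl5 (2.28 ± 0.43), Lpl (2.43 ± 0.42) and Il1b (4.33 ± 0.95) among the higher and the fatty acid synthase gene Fasn (-2.65 ± 0.41) and Bcl3 (-4.16 ± 0.73) among the lower. The maturation list had a median of 1.34 with 0 of 21 (1 adjusted over the list alone) higher (camera adjusted p = 0.000191, but adjusted p = 0.0696 with an estimated correlation), and in the 23-library fit 4 of 22 (11 adjusted over the list alone) rose with a median of 1.12 (camera adjusted p = 6.78e-09, and adjusted p = 0.00193 with an estimated correlation).

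Markers of other cells moved with PGPC in cDC1. Of the mast cell or basophil list 1 of 4 (2 adjusted over the list alone) rose with a median of 4.22, or 3.86 with absent genes at their bound (camera adjusted p = 5.49e-07, and adjusted p = 9.95e-05 with an estimated correlation), and Cpa3 was 152-fold (counting interval 41.8 to 1250) higher, or 62.7-fold without PGPC replicate 1. Granulocyte markers had a median of 2.44 (camera adjusted p = 0.0117, but adjusted p = 0.132 with an estimated correlation), macrophage markers 0.98 (adjusted p = 0.0247, but adjusted p = 0.271 with an estimated correlation) and B cell markers 1.13 (adjusted p = 0.0309, but adjusted p = 0.0968 with an estimated correlation). Granulocyte genes took 0.0904 ± 0.0526% of counts with PGPC and 0.0104 ± 0.00929% without. The count of 43 became 72 or 87 without PGPC replicate 1 or 2, and in the 23-library fit it became 118 without untreated replicate 1. Prss34, Parp12, Hs3st3b1, Tspan9 and Flt4 kept their calls there whichever library was left out (highest adjusted p = 0.0132 for Hs3st3b1), and that of Il12b was lost (0.0537). The median of all genes shifts by 1.01 under median-ratio scaling of all 36 libraries, and the share of called genes that are higher goes from 11.6% to 62.7%. The ribosomal RNA locus took 27.65 ± 11.76% of counts with PGPC and 53.2 ± 16.5% without, again without overlap.

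In cDC2 PGPC alone changed 0 genes (edgeR, 317 at an unadjusted p under 0.05), while DESeq2 called 64 and a fit of the 6 libraries alone 311, with the library of 3805 counts in the group. Without it the 23-library fit called 2 genes: Fam43a, higher by 4.32 ± 0.73 (adjusted p = 0.0216, n = 2 with PGPC), and the pseudogene Rab11b-ps2, at least 14.4-fold lower. Interferon-stimulated genes had a median of -1.08, or -0.87 with absent genes at their bound (camera adjusted p = 0.0469, but adjusted p = 0.833 with an estimated correlation) and lysosome genes -0.65 (adjusted p = 0.0469, but adjusted p = 0.833 with an estimated correlation). A set of spiked changes at log2 4 was recovered in 20% of genes at this depth over all libraries and in 88% in the 23-library fit. The effect of PGPC correlated across genes between the cell kinds with r = 0.00204 (rho 0.0644).

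Whether PGPC acts differently with LPS than without it was tested as an interaction. In cDC1 18 genes differed (17 higher, 1 lower), with a more positive PGPC effect in the presence of LPS for Flt4, Parp12, Aph1b, Ptprf and Lgr6 and a more negative one for Prss34. The 23-library fit called 159 (113 higher, 46 lower). There PGPC had a more negative effect with LPS than without it on Il12b (-5.35 ± 1.21, adjusted p = 0.0241), Cd40 (-3.34 ± 0.76, adjusted p = 0.0246) and Tnf (-3.04 ± 0.70, adjusted p = 0.0275; up to 0.0955, 0.0929 and 0.115 with 1 library left out). Without LPS the effect on Cd40 was 1.56 ± 0.55 and on Tnf 1.60 ± 0.53, and with it -1.78 ± 0.52 and -1.45 ± 0.46, all without a call. Il12b was higher with PGPC alone (adjusted p = 0.00719) and not called with LPS (-0.29 ± 0.64). The count was 0 without cDC1 LPS replicate 1 or 2, 5 without LPS replicate 3, 9 without LPS and PGPC replicate 1 or 3, and 33, 53 or 30 without PGPC replicate 1, 2 or 3. Under median-ratio scaling of all 36 libraries it was 1, and the share higher went from 94.4% to 0%. In cDC2 the interaction called 0 genes (edgeR, 272 at an unadjusted p under 0.05; DESeq2 49) and 4 in the 23-library fit: Fam43a, Vasp, Cdc25b and Rab11b-ps2.

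Alum asks how a particulate adjuvant changes these cells, but libraries of an alum group agreed poorly and held few genes. The counts and bounds below therefore cannot be read as effects on the cells alone. In cDC1 with alum against nothing 5161 genes changed (508 higher, 4653 lower). Hemoglobin genes led the rise: Hba-a1 was at least 11000-fold higher and Hbb-bt at least 8340-fold higher, and 4 of 5 (4 adjusted over the list alone) erythroid markers rose (camera adjusted p = 7.37e-08, and adjusted p = 0.00844 with an estimated correlation). Of the granulocyte markers 2 of 10 tested members rose and 1 fell (2 and 1 adjusted over the list alone), with S100a9 higher by 9.52 ± 3.00 (adjusted p = 0.0150). The camera test pointed upward while the median was -5.46, or 0.00 with absent genes at their bound (adjusted p = 0.0234, but adjusted p = 0.216 with an estimated correlation). The olfactory receptor gene Olfr539 was at least 592-fold higher. Of the cholesterol synthesis list 13 of 24 (16 adjusted over the list alone) fell and of the proliferation list 19 of 26 (22 adjusted over the list alone). Among all 11482 tested genes 4653 fell. Sirpa, Irf4, Clec9a and Irf8 were lower as well, with a highest adjusted p of 0.209, 0.385, 0.501 and 0.334 over the settings. Without alum replicate 1, which held 474 genes, the count was 568, so most of the 4653 lower calls were lost. The list counts above were not made without that library.

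In cDC2 with alum 8848 genes changed (860 higher, 7988 lower). S100a9 was at least 7500-fold higher, Camp at least 1800-fold higher and Ngp at least 1180-fold higher, all granule or calcium-binding protein genes of neutrophils, and Hba-a1 at least 8130-fold higher. Of the granulocyte markers 5 of 10 (4 adjusted over the list alone) rose (camera adjusted p = 1.56e-08, and adjusted p = 0.00159 with an estimated correlation). Of the erythroid markers 5 of 5 (5 adjusted over the list alone) (adjusted p = 1.94e-09, and adjusted p = 0.00159 with an estimated correlation). The vomeronasal receptor gene Vmn1r72 was at least 209-fold higher. Irf8 was at least 14.6-fold lower, and 22 of 24 (22 adjusted over the list alone) cholesterol synthesis genes and 14 of 16 (14 adjusted over the list alone) heat shock genes fell. Most genes did, with 7988 of all 11482 tested genes lower. Sirpa had a log2 fold change of 2.37 ± 1.59 (adjusted p = 0.167), which turned to -8.22 without alum replicate 4. Mitochondrial genes took 5.29 ± 2.01% of counts in cDC2 with alum and 5.98 ± 6.71% in cDC1 with alum.

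LPS with alum against LPS asks what the adjuvant adds to TLR4 activation. In cDC1 8555 genes changed (230 higher, 8325 lower). Tnf, without counts with alum, was at least 275-fold lower, Il12b at least 107-fold lower, the lysosomal gene Mpeg1 at least 2700-fold lower and the cytoskeletal gene Tln1 at least 1930-fold lower. Nlrp3, Casp1 and Gsdmd had no counts with alum either. Il1b was higher by 2.52 ± 1.12 (adjusted p = 0.0457, 1394 ± 756 against 243 ± 41.6 CPM), although this call was lost under most other settings (highest adjusted p = 0.242). Cep83 (4.47 ± 0.95) and Anp32b (3.12 ± 0.88) kept theirs. Il6 stood at 0.15 ± 1.32 (adjusted p = 0.937) and at -7.69 without LPS and alum replicate 2, and Ccr7 was lower (-3.86 ± 1.76, adjusted p = 0.0486, highest adjusted p = 0.264; -11.18 without that library). Of the proliferation list 26 of 26 (26 adjusted over the list alone) fell and of the cholesterol list 19 of 24 (19 adjusted over the list alone), while 4 of 5 (4 adjusted over the list alone) erythroid markers rose (camera adjusted p = 0.000138, and adjusted p = 0.0459 with an estimated correlation). Beside these lists, 8325 of all 11482 tested genes fell.

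In cDC2 9998 genes differed between LPS with alum and LPS (483 higher, 9515 lower). The libraries with LPS and alum correlated with each other at a Spearman rho of only 0.269 to 0.443. The chaperone gene Hspa8 was at least 2580-fold lower, Sirpa at least 1370-fold lower, the cathepsin gene Ctsd at least 1330-fold lower, Il1b at least 309-fold lower, Nlrp3 at least 208-fold lower and Tnf at least 101-fold lower. Hba-a1 was at least 1170-fold higher and S100a9 at least 555-fold higher. All 24 cholesterol synthesis genes and all 24 integrated stress genes tested fell, and 5 of 10 (3 adjusted over the list alone) granulocyte markers rose (camera adjusted p = 3.76e-08, and adjusted p = 0.00322 with an estimated correlation). Beside these lists, 9515 of all 11482 tested genes fell. For lists in the alum comparisons the fry test, which asks whether a list's genes move on balance one way and does not compare them with other genes, was mostly called downward, while camera, which compares a list with the other genes, was mostly not. For cytokines in cDC1 with alum camera pointed upward (adjusted p = 0.00442, but adjusted p = 0.475 with an estimated correlation) although the median was -4.65, or 0.00 with absent genes at their bound.

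LPS with PGPC and LPS with alum were also compared directly, under the same limit of the alum libraries. In cDC1 8742 genes changed (8538 higher with PGPC, 204 lower) and in cDC2 10125 (9593 and 532). Il12b was at least 90.6-fold higher with PGPC in cDC1, Gsdmd, which encodes the pore protein of pyroptosis, at least 334-fold higher, and Casp1 at least 22.8-fold higher. In cDC2 Il1b was at least 168-fold higher, Cxcl10 at least 155-fold higher and Sirpa at least 688-fold higher, and Hba-a1 was at least 3510-fold lower. Cholesterol synthesis genes were higher with PGPC, 19 of 24 (19 adjusted over the list alone) in cDC1 (camera adjusted p = 0.00481, but adjusted p = 0.721 with an estimated correlation) and 24 of 24 (24 adjusted over the list alone) in cDC2 (adjusted p = 0.00171, but adjusted p = 0.856 with an estimated correlation). Most genes moved the same way: of all 11482 tested, 8538 were higher with PGPC in cDC1 and 9593 in cDC2. With LPS and alum the libraries held 2168 ± 402 genes in cDC1 and 1599 ± 714 in cDC2.

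**Figure D5:**
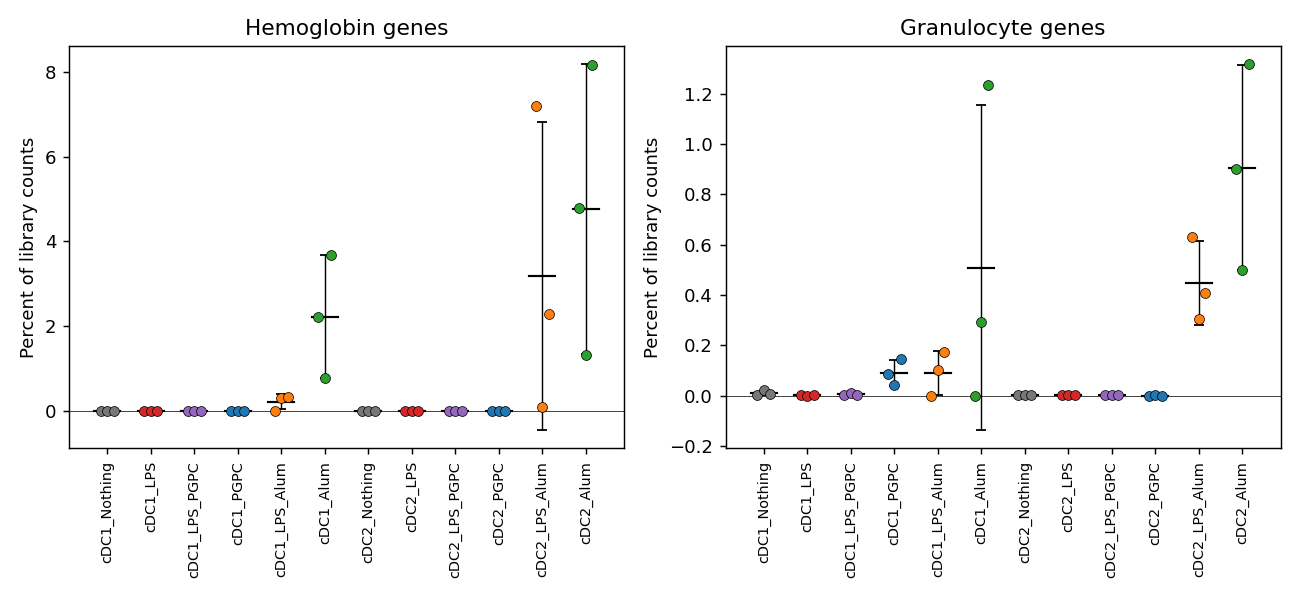
Share of counts in hemoglobin genes and in granulocyte genes (percent of library counts), 1 point per library, with the mean and standard deviation of each group. Hemoglobin shares reach a mean of 4.76% in cDC2 with alum and stay at or below 0.00123% in the groups without alum.

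The interactions with alum ask whether its effect differs with LPS present or between the cell kinds. Alum by LPS called 674 genes in cDC1 (68 higher, 606 lower) and 979 in cDC2 (133 higher, 846 lower; the share higher was 13.6%, and 38.2% under median-ratio scaling). Gsdmd had a more negative alum effect with LPS in both kinds, and Nlrp3, Hmox1, Cxcl10 and Sirpa in cDC2. With only the compared groups fitted neither cell kind had a call, with 0 genes in each. Without cDC1 alum replicate 3 the interaction of Gsdmd in cDC1 went from -10.32 to -0.55. In cDC2 that of Sirpa went from -18.54 to -7.99 without alum replicate 4. Without replicate 5 Nlrp3 went from -11.47 to -2.92 and Cxcl10 from -11.99 to -6.33. The calls of Gsdmd in cDC1, Nlrp3 and Cxcl10 were lost there (adjusted p = 1 for each) and that of Sirpa was kept. The effect of adding alum to LPS differed between cDC2 and cDC1 in 2081 genes (560 higher, 1521 lower in cDC2; 26.9% higher, and 39.9% under median-ratio scaling), and in 45 with only the compared groups fitted. Il1b, which was higher with alum in cDC1 and without counts with it in cDC2, kept that call under every setting. Without cDC1 alum replicate 1 the cDC1 count was 1474, without replicate 2 it was 362 and without replicate 3 169. The cDC2 count was 626 without alum replicate 5 and 646 without replicate 6.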

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

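The tests of the 3 patterns weighed here were chosen after the result was seen, except the thinning of the libraries with LPS and PGPC. Each result with a value in the next 2 paragraphs differed between groups by a test of the difference itself, the interaction in the edgeR fit of all 36 libraries. Several rest on groups without counts, where the size of the estimate depends on the prior count.

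PGPC acted differently on cDC1 with and without LPS in 18 genes, with log2 interactions of 8.42 for Flt4, 8.51 for Aph1b, 9.2 for Ptprf, 9.14 for Parp12, 12.92 for Lgr6 and -13.49 for Prss34. LPS acted differently on cDC2 and cDC1 in 6 genes, among them Cxcl14 (7.99), Enpp4 (5.43), C130026I21Rik (5.18), Tnfrsf13c (8.04) and Cst7 (7.21). Many of these calls hung on single libraries. Without LPS replicate 1 or 2 of cDC1 all of the 18 were lost, and Lgr6 went to 7.78 without LPS and PGPC replicate 1 (adjusted p = 1). Without untreated cDC2 replicate 5 each of the 5 genes named for LPS lost its call (adjusted p up to 0.0673), and Cst7 went to 11.01 without replicate 4.

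The limit of the alum libraries given above holds for this paragraph, so its values cannot be read as effects on the cells alone. The contrast of alum with no alum differed with and without LPS in 674 genes of cDC1, with -10.32 for Gsdmd. It differed in 979 genes of cDC2, with -14.95 for Hmox1, -9.55 for Gsdmd, -11.47 for Nlrp3, -11.99 for Cxcl10 and -18.54 for Sirpa. With only the compared groups fitted the counts were 0 and 0. Gsdmd in cDC1 went to -0.55 without alum replicate 3. In cDC2 Sirpa went to -7.99 without alum replicate 4, with its call kept, and Nlrp3 and Cxcl10 to -2.92 and -6.33 without replicate 5. The contrast of LPS and alum with LPS differed between the cell types in 2081 genes, with -11.98 for Hmox1, -11.02 for Il6, -16.54 for Il1b, -11.64 for Cxcl10, -7.94 for Ccr7 and -10.37 for Irf8. With only the compared groups fitted 45 genes were called, and of these 6 Il1b alone kept its call. Without replicate 2 of cDC1 with LPS and alum Il6 went to -3.15 (adjusted p = 0.952), Cxcl10 to -5.55 (adjusted p = 0.389) and Ccr7 to -0.68 (adjusted p = 1). Irf8 went to 1.43 without replicate 1 of that group. Ccr7 went to -12.48 without replicate 6 of cDC2 with LPS and alum.

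The alum libraries held counts in 474 to 2627 genes. Lower depth does not account for this: other libraries thinned to the total of each alum library still held at least 3.19 times as many genes. Erythroid and granulocyte marker genes took at most 14.3% of the counts outside the ribosomal RNA locus, so these genes themselves were not the main content. Other transcripts of such cells were not counted, so this share cannot exclude them as the source of more of the RNA. Little dendritic cell RNA beside a nonspecific background was tested with a sign asked of all 12 libraries. Receptor genes for smell and pheromones, which these cells do not use, took 0.0106 to 3.17% of counts (median 0.255%) against 0.00251 to 0.0166% (median 0.00823%) in the 23 libraries, but 11 and not all 12 alum libraries lay above the highest other one. The bound set for this test was therefore not met. The library below it, replicate 1 of cDC1 with LPS and alum at 0.0106%, lay within the range of the 23 libraries. Its share shows no excess of these receptor genes but cannot exclude a background of other genes. This explanation therefore stays open for all 12. Whether alum killed the cells, took up their RNA or disturbed the library reaction was not tested, and the biological effect of alum on gene expression stays open beside these.

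Lipid genes were higher as lists with LPS and PGPC than with LPS alone, in libraries that were deeper. After all 12 libraries were thinned to 980490 counts, the cholesterol synthesis list in cDC2 kept a median of 1.41 (1.56 unthinned; camera adjusted p = 8.31e-17), and the lipid handling list in cDC1 0.824 (0.861 unthinned, adjusted p = 0.00372), which argues against depth. With an estimated correlation, unthinned and over all 36 libraries, the lists in cDC1 were without a call (adjusted p = 0.457 for lipid handling and adjusted p = 0.690 for cholesterol synthesis). The cholesterol list in cDC2 kept its call (adjusted p = 0.000410), and in the 23-library fit lipid handling in cDC1 had one (adjusted p = 0.00819). Cholesterol synthesis genes in cDC1 had 0.404 (0.401 unthinned), with adjusted p = 0.053 in place of 0.0374. RNA from macrophages could raise lipid genes, and the macrophage list had a median of 0.219 in cDC1 and 0.729 in cDC2 in the 23-library fit. Both are above 0, so this cannot be told apart from a response of the cells to the lipid. The biological explanation, a response to PGPC, is untested beyond the comparison itself.

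Genes of basophils and mast cells were higher in cDC1 with PGPC. They were not from 1 library alone: the lowest level of Prss34 or Cpa3 in a PGPC library was 7.82 CPM, above every untreated library. Of 6 markers with counts, 4 were higher in every PGPC library than in every untreated one (5% by chance for each): Cpa3 (16.3 ± 11.3 against 0.089 CPM), Fcer1a (4.71 ± 2.28 against 0), Prss34 (38.4 ± 10.3 against 0) and Gata2 (6.15 ± 2.46 against 1.98), while Mcpt8 (5.96 ± 6.71) and Hdc (1.19 ± 2.07) were not. These markers belong to the list that gave the pattern. Their count therefore cannot tell RNA of basophils or mast cells from expression by cDC1. RNA from such cells may be present in the PGPC cultures, and no sort or gate that would remove them is given in the labels. Expression of these genes by cDC1 stays open as the biological explanation.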

How the results depend on the processing

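The fit without the alum libraries and the shallowest library was chosen after seeing the data. So were the libraries left out of it and its median-ratio scaling, while all other alternatives were chosen before. Unless said otherwise the cause of a change in the counts was not tested. In the 23-library fit the biological coefficient of variation is lower (0.545 against 0.833), and the counts were 2235 for LPS in cDC1, 259 for PGPC, 241 for LPS with PGPC against LPS. For the same in cDC2 they were 1062, 2 and 48, with 1265 for the cell types, 159 and 4 for PGPC by LPS in cDC1 and cDC2, 166 for LPS by cell type and 1 for LPS with PGPC by cell type. With only the groups compared they were 2503, 8 and 353 in cDC1. In cDC2 they were 1172, 311 and 13, with 5138 for alum, 4823 for LPS with alum against LPS and 6712 for LPS with PGPC against LPS with alum. This fit gave 1860 for the cell types, 58 and 6 for PGPC by LPS, 0 and 0 for alum by LPS, 242 for LPS by cell type and 45 for LPS with alum by cell type. DESeq2 called 2091, 360 and 86 in cDC1, and 395, 64 and 29 in cDC2. It called 491 for the cell types, 367 and 49 for PGPC by LPS, 7279 for alum by LPS in cDC1, 80 for LPS by cell type and 15 for LPS with PGPC by cell type. Median-ratio scaling of all 36 libraries rests on 12 genes and gave 1281 for LPS in cDC1 and 137 in cDC2, 0 and 0 for LPS with PGPC against LPS, 1 for PGPC by LPS in cDC1, 1096 for alum by LPS in cDC1 and 0 for LPS by cell type. No filter gave 91 for PGPC in cDC1, 24 for LPS with PGPC against LPS, 73 for PGPC by LPS and 30 for LPS by cell type. With the replicate number as a block, the counts were 143 for LPS in cDC2, 0 and 0 for LPS with PGPC against LPS, 3 for PGPC by LPS in cDC1 and 942 for LPS with alum by cell type. Whether the numbers pair the libraries stays open. Over all libraries, residuals of the same number correlated with a median of 0.024 in cDC1 and 0.0035 in cDC2. Without the alum and cDC2 PGPC libraries these medians were 0.0717 and 0.0359, with highest values of 0.221 and 0.611. Pairs of other numbers had medians of -0.0319 and -0.0053 there. A block could not be fitted for the cell types.

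With each library left out, counts ranged from 231 to 456 for LPS in cDC1, 32 to 87 for PGPC, 568 to 5077 for alum, 0 to 30 for LPS with PGPC against LPS, 8307 to 9023 for LPS with alum and 8531 to 9201 for LPS with PGPC against LPS with alum. In cDC2 these were 31 to 139, 0 to 0, 6820 to 8752, 0 to 0, 9635 to 9958 and 9840 to 10074. They were 2 to 72 for the cell types, 0 to 53 and 0 to 0 for PGPC by LPS, 169 to 1474 and 626 to 1030 for alum by LPS, 0 to 17 for LPS by cell type, 0 to 1 for LPS with PGPC by cell type and 1500 to 1959 for LPS with alum by cell type. Single genes turned when 1 library was left out: without replicate 2 of cDC1 with LPS and alum Il6 went to -7.69 (otherwise up to 0.74) and S100a9 to -2.95 (up to 6.23) against LPS. For LPS with PGPC against LPS with alum Il6 went there to 5.90 (otherwise down to -2.54) and Camp to 0.27 (down to -9.58), and Ltf went to 6.62 without replicate 3 (down to -8.90). Sirpa went to -8.22 in cDC2 with alum without replicate 4 (otherwise up to 2.96). Without replicate 1 of cDC1 with LPS and alum Irf8 went to -7.88 for alum by LPS in cDC1 (otherwise up to 5.84) and to 1.43 for LPS with alum by cell type (down to -10.98).

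Camera called 47 list tests, 15 with an estimated correlation, and fry, which asks another question, called 127. For marker lists these were 28, 12 and 55. The correlation of effects between the cell types moved from 0.511 to 0.584 for LPS among genes with a mean log2 CPM above 3 and to 0.474 in DESeq2. It moved from 0.00204 to 0.0433 for PGPC (CPM limit) and from 0.48 to 0.414 and 0.401 for alum. It went from 0.346 to 0.299 and 0.0382 for LPS with alum, and from 0.344 to 0.293 and 0.035 for LPS with PGPC against LPS with alum. Left-out libraries gave 0.408 to 0.529, -0.0515 to 0.0574, 0.427 to 0.498, 0.327 to 0.394 and 0.326 to 0.393 for these, and 0.0436 to 0.33 for LPS with PGPC against LPS. Median-ratio scaling of all 36 libraries shifted the median log2 fold change of all genes by 1.31 for LPS, 1.01 for PGPC, 0.77 for alum, -0.442 for LPS with PGPC and -0.554 for LPS with alum in cDC1. The shifts were 0.153, -0.386 and 0.135 for LPS, PGPC and LPS with alum in cDC2, -0.212 for LPS with PGPC against LPS with alum in cDC2 and 0.537 for the cell types, and at most 0.0935 in the 23-library fit. For the interactions it was -1.44 and 0.28 for PGPC by LPS, -1.27 for alum by LPS in cDC1, -1.17 for LPS by cell type, 0.33 for LPS with PGPC by cell type and 0.626 for LPS with alum by cell type. Depth limits the comparison of PGPC in cDC2, where 1 library held 3805 counts. All comparisons with alum are limited by the 474 to 2627 genes detected, which lower depth does not account for.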

Other observations

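The tests of other splits of the libraries were chosen after the result was seen. Further gene groups set the untreated cells apart. Interferon-stimulated genes had a median log2 fold change of 2.37, or 2.31 with absent genes at their bound in cDC2 against cDC1 (camera adjusted p = 4.94e-06, but adjusted p = 0.148 with an estimated correlation). Of its members 0 of 36 (4 adjusted over the list alone) rose, and Oasl2 (3.91 ± 0.86) and Oas3 (3.44 ± 0.74), sensors of viral RNA, rose in the 23-library fit. Genes of the unfolded protein response had a median of -0.90 (camera adjusted p = 0.00117, but adjusted p = 0.148 with an estimated correlation), and Herpud1 (-3.33 ± 0.50, adjusted p = 0.000173) and Manf (-2.04 ± 0.47) fell in that fit. Of the proliferation list 1 of 26 (8 adjusted over the list alone) fell (median -1.48, camera adjusted p = 1.66e-05, but adjusted p = 0.148 with an estimated correlation). MHC class II genes had a median of -1.57 (camera adjusted p = 0.0165, but adjusted p = 0.264 with an estimated correlation). H2-DMa (-3.05 ± 0.49), which helps load peptides, was lower in the 23-library fit. Granulocyte precursor markers had -6.23, or -3.66 with absent genes at their bound (adjusted p = 0.000488, but adjusted p = 0.0591 with an estimated correlation).

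LPS, in the 23-library fit, also moved genes of lysosomes and lipids in cDC1. The proteases Ctsd (-3.54 ± 0.45, adjusted p = 6.56e-06), Ctsl (-3.38 ± 0.45) and Ctsb (-3.02 ± 0.45) fell. The MHC class II genes H2-Ab1 (3.19 ± 0.51) and H2-Eb1 (3.41 ± 0.57) and the cystine transporter gene Slc7a11 (3.94 ± 0.53) rose. Plin2 fell with LPS by 3.24 ± 0.37 on the log2 scale and rose by 2.62 ± 0.36 when PGPC was added, and Lpl had -3.20 ± 0.45 and 3.39 ± 0.45. In cDC2 Lpl had -3.30 ± 0.44 with LPS and 2.38 ± 0.43 with PGPC added. The chemokine gene Ccl22 rose by 8.12 ± 0.63 in cDC1 and 5.13 ± 0.55 in cDC2. These calls held in the 23-library fit with each library left out, except that of Lpl in cDC2 with PGPC (adjusted p up to 0.0618).

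Splits of 6 libraries into groups of 3 number 10, too few for a share under 0.05. With the compared groups fitted alone, the real split and the highest other called 2503 and 0 genes for LPS in cDC1, 8 and 0 for PGPC and 4378 and 0 for alum. They called 353 and 1 for LPS with PGPC against LPS, 6087 and 0 for LPS with alum against LPS, and 6746 and 0 for LPS with PGPC against LPS with alum. In cDC2 they called 1172 and 0, 311 and 27, 5138 and 0, 13 and 406, 4823 and 0, and 6712 and 0, and for the cell types 1860 and 0. Of the 10 splits 1, the real one, called as many genes in each of these except LPS with PGPC against LPS in cDC2, where 2 did. The split there that called 406 genes, many times the real 13, points to a structure of the 6 libraries other than the treatment. What that structure is was not tested, and a shared replicate number is not excluded.

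For the interactions 40 splits were drawn, each within an arm of the compared groups. Such a split can carry the main effect of a treatment into the interaction, so it gives no measure of chance for it, and these splits cannot tell. For PGPC by LPS 1 of 40 called as many genes as the real split in cDC1 (real 58, highest other 8) and 3 of 40 in cDC2 (real 6, highest other 19). For LPS by cell type 2 of 40 did (real 242, highest other 388), and for LPS with alum by cell type 4 of 40 (real 45, highest other 5317). For alum by LPS in cDC1 and cDC2 and LPS with PGPC by cell type the real split called 0 genes in this fit, so that all 40 of 40 called as many, with highest others of 6750, 6160 and 271.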
